A study of Mus musculus with 6 samples.

How the data were processed

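RNA sequencing libraries were made from mouse embryonic fibroblasts of C57BL/6 embryos of 14 days at passage 16, grown in DMEM with 10% fetal bovine serum, and RNA was isolated with RNeasy columns, per the labels' protocols. Reads were single and 51 bp long, per the labels. Each of the 6 libraries had 1 deposited file of gene counts, the number of reads per Ensembl gene summed over its exons and not normalized. Per the file headers, the authors made these counts with featureCounts 1.6.2 from an annotation of Ensembl release 83 on GRCm38 with mm10 chromosome names, by exon and gene identifier. Per the file headers, no strand option and no option for multimapping reads or for reads in several genes was set, so reads over exons of more than 1 gene, on either strand, and reads that map to several places are left out of the counts by the program's default. Per the submitters' processing notes, Trimmomatic 0.33, FastQC 0.11.2, Subread 1.6.2 and featureCounts 1.2.6 were used, and the last version differs from that in the file headers. The notes also name the builds GRCm38, mm10 and hg38 without a role, and all coordinates here are those of the files.

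The files held 46983 genes, of which 46488 (98.9%) were matched to a symbol by identifier, and no row named anything other than a gene. Total counts ran from 15598566 to 23681718 per library. A count of 3 corresponds to 0.127 to 0.192 CPM, the level below which a gene at 0 in a library cannot be told from a low one. Counting intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. The 37 mitochondrial genes had 0 counts in all libraries, so no mitochondrial share was computed.

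Groups were taken from the titles of the samples. Genes were kept by edgeR's filterByExpr, which left 15199, scaled with TMM factors, and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test with robust dispersion, 3 null-labelled against 3 wild-type-labelled libraries, with no covariate. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. A fold against a group without counts used 3 counts over its 3 libraries, and a group with 1 to 3 counts was given with an exact binomial 95% counting interval of the ratio. Gene lists and chromosomes were tested against all other genes with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, adjusted over the 22 functional lists or the 20 chromosomes. Of the genes in lists, 11 stood in more than 1. The 7 marker lists of other cell types were only counted. Intervals of chromosome medians came from 2000 bootstrap draws of genes.

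The tests of genes, lists and chromosomes, the alternatives, the lists and the rule for named genes were chosen before the data were examined. The tests of explanations for the differences were not part of this plan. Those on Sphk2, on the origin of the cells and on an extra copy of chromosome 8 were chosen after the values were seen. The predictions of the other such tests were written before those tests were run. Some of them concern chromosome 8, which the plan did not name and which had the highest median of the 20 chromosomes. The choice of that chromosome thus cannot count as made in advance. Named were Sphk2, Sphk1 and Trp53, and the 8 genes with the largest fitted log2 fold change in each direction. The latter needed an adjusted p under 0.05, an average log2 CPM of at least 3 and groups that did not overlap, and predicted models were left out. Also named, among members past 0.05 with an average log2 CPM of at least 1, were the 3 of each functional list and the 2 of each marker list with the largest differences. Dbp and Rpl18 were named after their overlap with Sphk2 was seen. The rule took 98 genes, of which 1 is not reported here.

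The test was checked on counts simulated for the 15199 genes of the comparison of null-labelled with wild-type-labelled libraries, with 200 genes changed. It recovered 52% of 50 genes changed by 1.2-fold, 72% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, and called 6 of 14999 unchanged genes. Camera called a list shifted by 1.5-fold and 0 of 21 unshifted lists. Genes were simulated independently and few were changed. The check therefore does not cover lists with correlated members or data in which most genes differ, as here. As alternatives, median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of over 1 CPM in 3 libraries, a block for the replicate number, an adjusted p under 0.01, an estimated correlation in camera and leaving out each library in turn were run.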

Results

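Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts, connective tissue cells grown out of embryos. The cells came from C57BL/6 embryos of 14 days and were used at passage 16. Of the 6 libraries, 3 were labelled wild type and 3 SphK2 null. SphK2, encoded by Sphk2, is sphingosine kinase 2, which phosphorylates sphingosine to sphingosine-1-phosphate (S1P), a lipid signal. The series title sets the work in the stroma of breast tumours, and the comparison asks which transcripts differ between fibroblasts of the 2 genotypes. The libraries labelled wild type held 23681718, 15598566 and 19535503 counts in genes, and those labelled SphK2 null held 19148434, 16804841 and 18403189. Below, "wild-type-labelled" and "null-labelled" refer to these labels. Where a pair of values is joined by "against" without a group, the wild-type-labelled value comes first. Levels are CPM (counts relative to the library total, scaled for composition with TMM factors), as mean ± SD over 3 libraries.

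Sphk2 transcripts were present in all 6 libraries and were higher in the null-labelled ones, against the direction that the label names. Sphk2 stood at 27.3 ± 0.907 CPM (SD, n = 3) in wild-type-labelled and 50.02 ± 1.35 CPM (SD, n = 3) in null-labelled libraries. The log2 fold change was 0.87 ± 0.051 (SE), with an edgeR quasi-likelihood adjusted p = 4.48e-64. The counts were 654, 418 and 503 in the wild-type-labelled libraries and 964, 883 and 921 in the null-labelled ones. Sphk2 (ENSMUSG00000057342) lies on the minus strand of chromosome 7 from 45709467 to 45718002 in the mm10 build. Of its 4159 exonic bases, 491 (11.8%) also belong to exons of Dbp and 373 (8.97%) to exons of Rpl18, both on the plus strand. Counting did not use strand, and reads over exons of more than 1 gene were left uncounted, so these stretches add nothing to the count of either gene. Dbp (log2 fold change 1.80 ± 0.090 SE) and Rpl18 (0.76 ± 0.029 SE) were higher in the null-labelled libraries too. The deposited counts sum all exons, and which part of the gene the null allele lacks was not given in the sources used here. The counts therefore do not settle the genotype of either group, and every direction given here is between labels.

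**Figure D1:**
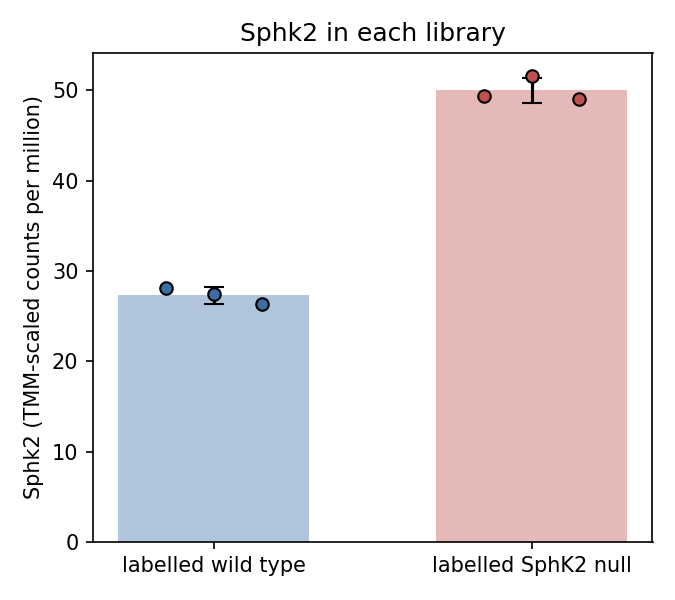
Sphk2 level in CPM for each library (points), with the group mean (bar, axis from 0) and SD (error bar, n = 3). The null-labelled libraries lie between 49.1 and 51.6 CPM and the wild-type-labelled ones between 26.3 and 28.1 CPM.

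Sphk1, the isoenzyme that makes the same lipid, was lower in the null-labelled libraries, at 13.2 ± 0.888 against 7.09 ± 0.072 CPM (SD, n = 3), with a log2 fold change of -0.91 ± 0.095 (SE) and an edgeR adjusted p = 4.13e-21. Trp53, which encodes the tumour suppressor p53, stood at 224 ± 1.94 against 226 ± 3.44 CPM (SD, n = 3), with an edgeR adjusted p = 0.615.

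Expression differed between the labels across most of the transcriptome, and the largest differences were losses. Of the genes with at least 1 CPM in the wild-type-labelled libraries, 171 had no count in the null-labelled ones, and 14 genes showed the reverse. At least 1145-fold lower was Pcdh19, a protocadherin of cell adhesion, with 3571 counts over the wild-type-labelled libraries and 0 over the null-labelled ones. Also without a count were Lrch2 (at least 584-fold lower), the zinc finger transcription factor Zfp521 (at least 493-fold), the adhesion receptor Adgrl3 (at least 471-fold), the sulfotransferase Chst2 (at least 389-fold), Sfmbt2 (at least 339-fold), the tachykinin precursor Tac1 (at least 321-fold) and the homeobox gene Hlx (at least 316-fold). These bounds set the group at 0 to 3 counts over its 3 libraries. The genes were ranked by fitted log2 fold change. Some genes with counts in both groups, such as Col4a5 (1942 counts against 1, ratio 1868), have a point ratio above these bounds. Such a ratio is not set at 3 counts as the bounds are, so the sizes cannot be compared directly. The counting interval of the Col4a5 ratio, 335 to 73800, starts below the bound of Pcdh19. Col4a5 is thus not shown to differ by more than Pcdh19. The largest gains were in Chst5, another sulfotransferase, which went from 0.087 ± 0.075 to 41.4 ± 1.30 CPM (SD, n = 3), and in Rasgrp2, an activator of Rap GTPases, from 0.132 ± 0.058 to 56.8 ± 1.29 CPM (SD, n = 3). Dok7 (log2 fold change 8.02 ± 0.20 SE), the growth factor Bmp7 (7.57 ± 0.19 SE), AU018091 (7.47 ± 0.18 SE), the septin Sept4 (7.33 ± 0.10 SE), Efr3b (7.30 ± 0.080 SE) and Lypd3 (7.16 ± 0.21 SE) were also higher. The largest edgeR adjusted p among all the genes of this paragraph was 1.46e-252.

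Of 15199 genes tested, 5795 were higher and 6245 lower in the null-labelled libraries at an edgeR quasi-likelihood adjusted p under 0.05, together 79.2%. By over 2-fold, 1583 were higher and 2399 lower, so that 66.9% of the genes past the threshold differed by less. Over 32-fold, among genes of at least 1 CPM in the higher group, 842 were lower and 112 higher. In 12151 genes (79.9%) the groups did not overlap, where chance gives 10%. The labels do not say that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

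The libraries of a group were close to identical. Within a group, log2 CPM correlated across genes at Pearson's r from 0.995 to 0.996 in the 6 pairs, and between groups at 0.812 to 0.815 in the 9 pairs, where genes are not independent replicates. The first principal component held 97.1% of the variance and separated the labels. The chi-square of counts within a group was 1.44 to 2.04 per degree of freedom, above the sampling noise in every pair, so no pair was treated as 1 library deposited more than once. This does not show whether the libraries came from separate cultures. The common biological coefficient of variation was 2.24%.

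Transcripts of the extracellular matrix were lower in the null-labelled libraries as a group. Of 38 tested matrix proteins and crosslinkers, 33 were lower and 4 higher, with a median log2 fold change of -5.66 (-5.51 with its 2 members at 0 counts set to their bound). Fn1, the adhesive glycoprotein fibronectin, stood at 2036 ± 43.7 CPM in wild-type-labelled and 3.37 ± 0.357 CPM in null-labelled libraries (SD, n = 3). Thbs2, thrombospondin of the matrix, stood at 392 ± 10.2 against 0.665 ± 0.071 CPM (SD, n = 3), and Efemp1, a fibulin, was at least 206-fold lower. Of 21 collagens, 17 were lower and 3 higher (median -1.98). Col5a2 stood at 445 ± 9.91 against 1.05 ± 0.162 CPM and Col11a1 at 253 ± 3.67 against 0.649 ± 0.014 CPM (SD, n = 3). Col4a5 had 1942 counts against 1, a ratio of 1868 with a 95% counting interval of 335 to 73800. Of 36 matrix proteases and inhibitors, 31 were lower and 5 higher (median -2.64). Among these, Serpine2, an inhibitor of serine proteases, stood at 21.5 ± 0.989 against 0.068 ± 0.118 CPM (SD, n = 3). The aggrecanase Adamts5 had 608 counts against 1 (ratio 585, 95% counting interval 105 to 23100) and Adamts9 had 1365 against 3 (ratio 438, interval 149 to 2130). Camera with a preset correlation gave adjusted p = 3.15e-08 for the matrix proteins, 9.86e-05 for the collagens and 1.39e-05 for the proteases. The collagens had an adjusted p = 0.204 with an estimated correlation, and each of the other lists here had an adjusted p = 0.0437 with an estimated correlation.

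Markers of fibroblast activation, known also from fibroblasts of tumours, were mostly lower. Of 27 tested, 22 were lower and 4 higher, with a median log2 fold change of -2.83, which stayed at -2.83 with the member at 0 counts set to its bound. Podoplanin (Pdpn) stood at 70.4 ± 3.28 against 0.071 ± 0.027 CPM and the sialomucin Cd34 at 266 ± 1.19 against 0.428 ± 0.162 CPM (SD, n = 3). Thy1, a surface antigen of fibroblasts, was at least 82.1-fold lower. Because the list also holds general fibroblast genes such as Thy1, its fall does not tell lower activation from a loss of fibroblast transcripts at large. Of 22 contractile genes, 18 were lower and 3 higher (median -1.24). Acta2, smooth muscle actin, stood at 202 ± 7.51 against 0.941 ± 0.063 CPM, Tagln, an actin-binding protein, at 37.1 ± 1.68 against 1.08 ± 0.079 CPM, and the myosin light chain Myl9 at 20.2 ± 1.11 against 1.13 ± 0.199 CPM (SD, n = 3). Camera gave adjusted p = 1.39e-05 for the activation markers and 9.52e-05 for the contractile genes. These became adjusted p = 0.136 and adjusted p = 0.159 with an estimated correlation.

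Genes tied to TGF-beta signalling and to YAP and TAZ, transcriptional coactivators of the Hippo pathway, went mostly the same way. Of 28 TGF-beta response genes, 23 were lower and 5 higher (median -0.84). Grem1, a secreted antagonist of bone morphogenetic proteins, stood at 698 ± 9.42 against 1.598 ± 0.348 CPM (SD, n = 3). Bambi, a pseudoreceptor that dampens TGF-beta signalling, had 622 counts against 1 (ratio 598, 95% counting interval 107 to 23700), and Pmepa1, another negative regulator, had 878 against 3 (ratio 282, interval 96.0 to 1370). These named members are antagonists of the pathways that the list covers. Of 24 YAP/TAZ targets, 17 were lower and 6 higher, with a median of -0.81 also when the member at 0 counts was set to its bound. Fjx1 had 1309 counts against 1 (ratio 1259, interval 226 to 49800), the forkhead factor Foxf2 had 729 against 1 (ratio 701, interval 125 to 27700), and Rbms3 stood at 12.6 ± 0.904 against 0.198 ± 0.060 CPM (SD, n = 3). Camera gave adjusted p = 0.000267 for the TGF-beta list and 0.0152 for the YAP/TAZ list. These became adjusted p = 0.136 and adjusted p = 0.159 with an estimated correlation.

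Secreted signals were lower as well. Of 25 chemokines, cytokines and prostaglandin enzymes, 21 were lower and 3 higher (median -2.23, also with the member at 0 counts at its bound). The chemokine Cxcl14 had 1398 counts against 1 (ratio 1345, 95% counting interval 241 to 53200), the alarmin Il33 had 560 against 1 (ratio 539, interval 96.3 to 21300), and the neutrophil chemokine Cxcl5 had 852 against 2 (ratio 410, interval 113 to 3390). Of 28 secreted growth factors, 24 were lower and 2 higher (median -3.47, and -3.51 with the member at 0 counts at its bound). Ptn, pleiotrophin, stood at 474 ± 6.54 against 1.15 ± 0.038 CPM, Pdgfc, a ligand of the platelet-derived growth factor receptor, at 106 ± 4.14 against 0.211 ± 0.136 CPM, and Fgf10 at 41.1 ± 1.52 against 0.089 ± 0.027 CPM (SD, n = 3). Camera gave adjusted p = 3.39e-05 and 1.76e-05, and each had an adjusted p = 0.0437 with an estimated correlation.

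Of 39 interferon response genes, 37 were lower and 2 higher in the null-labelled libraries, with a median log2 fold change of -2.40, also with the member at 0 counts at its bound. Ifi44 stood at 63.8 ± 12.4 against 0.200 ± 0.042 CPM, the antiviral effector Ifit3 at 14.1 ± 3.57 against 0.106 ± 0.048 CPM and Rtp4 at 43.1 ± 7.61 against 0.482 ± 0.209 CPM (SD, n = 3). Camera gave adjusted p = 3.52e-08, and adjusted p = 0.303 with an estimated correlation, where that correlation between members was 0.58. Class I antigen presentation did not pass the test, with 7 higher and 11 lower of 20 (camera adjusted p = 0.467). Its members went both ways, with Tapbpl (log2 fold change 2.30 ± 0.082 SE) and the peptide transporter subunit Tap2 (1.59 ± 0.060 SE) higher and H2-T22 (-1.29 ± 0.067 SE) lower.

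Genes of sterol synthesis were lower by a moderate amount. Of 25, 21 were lower and 2 higher (median -1.01, camera adjusted p = 3.39e-05, and adjusted p = 0.136 with an estimated correlation). Squalene epoxidase, Sqle, had a log2 fold change of -1.595 ± 0.032 (SE), and Fdps, farnesyl diphosphate synthase, -1.49 ± 0.090 (SE). The cell cycle and DNA replication list was the only one of the 22 functional lists that camera called higher. Of its 54 genes, 36 were higher and 15 lower (median 0.21, camera adjusted p = 0.00623, and adjusted p = 0.258 with an estimated correlation). E2f2, a transcription factor of S phase entry, stood at 19.3 ± 1.08 against 96.5 ± 1.75 CPM (SD, n = 3). The replication licensing factor Cdt1 had a log2 fold change of 1.00 ± 0.028 (SE), while Cdc45, part of the replicative helicase, had -1.20 ± 0.041 (SE).

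Among the developmental groups, imprinted genes were mostly lower, and so were all tested Hox genes of the HoxA cluster. Of 24 imprinted genes, 19 were lower and 5 higher (median -6.44, and -6.76 with the member at 0 counts at its bound). Ndn had 3562 counts against 3 (ratio 1142, 95% counting interval 391 to 5540), the long noncoding RNA H19 had 1894 against 2 (ratio 911, interval 252 to 7530), and the zinc finger gene Plagl1 was at least 97.2-fold lower. Of 25 Hox genes, 15 were lower and 4 higher (median -0.34, also with its 2 members at 0 counts at their bound). By cluster, a split made after the values were seen, all 10 HoxA genes were lower. Of the other 15 genes 5 were lower, 4 higher and 6 not past the threshold, and 4 of these 5 lower genes were in HoxD. Hoxa5 had 729 counts against 1 (ratio 701, interval 125 to 27700), Hoxa11 stood at 44.3 ± 0.844 against 0.089 ± 0.027 CPM and Hoxa7 at 30.7 ± 1.99 against 0.129 ± 0.114 CPM (SD, n = 3). Camera gave adjusted p = 0.00011 for the imprinted and 0.00879 for the Hox genes. These became adjusted p = 0.136 and adjusted p = 0.161 with an estimated correlation.

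The lists closest to the targeted enzyme did not pass camera, although single members differed. Of 30 sphingolipid enzymes, 5 were higher and 16 lower (median -0.12, camera adjusted p = 0.226). Smpd3, a neutral sphingomyelinase, stood at 0.865 ± 0.205 against 6.18 ± 0.693 CPM, the lysosomal galactosylceramidase Galc at 26.3 ± 1.65 against 7.59 ± 0.308 CPM, and the sphingomyelin synthase Sgms2 at 55.5 ± 1.72 against 29.3 ± 0.992 CPM (SD, n = 3). Of 14 S1P receptors and transporters, 4 were higher and 8 lower (median -0.32, camera adjusted p = 0.361). The receptor S1pr1 had 1055 counts against 1 (ratio 1015, 95% counting interval 182 to 40100), and S1pr3 had 364 against 1 (ratio 350, interval 62.5 to 13900). Abca1, a lipid exporter, stood at 55.0 ± 1.57 against 0.158 ± 0.099 CPM (SD, n = 3).

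The other 5 functional lists also missed the threshold, with members that went both ways. Of 32 p53 targets, 14 were higher and 12 lower (camera adjusted p = 0.467), and the median of 0.02 (also with the member at 0 counts at its bound) and the mean of -0.08 differed in sign. The median also turned, to -0.05 without null-labelled replicate 3, to -0.0011 without wild-type-labelled replicate 2 and to -0.06 with no filter on low counts. The cell cycle inhibitor Cdkn1a stood at 11.6 ± 2.89 against 120 ± 1.87 CPM (SD, n = 3), the stress cytokine Gdf15 had a log2 fold change of 3.85 ± 0.26 (SE), and the DNA damage sensor Ddb2 had -3.51 ± 0.27 (SE). Of 31 immediate-early genes, 17 were higher and 12 lower (camera adjusted p = 0.384), with a median of 0.26 and a mean of -0.22. Egr1 stood at 20.9 ± 0.839 against 0.339 ± 0.093 CPM (SD, n = 3), Dusp6, a phosphatase of ERK, had a log2 fold change of -2.90 ± 0.050 (SE), and Ier3 had 2.24 ± 0.042 (SE). Of 33 glycolysis and hypoxia genes, 21 were higher and 9 lower (median 0.14, camera adjusted p = 0.0587), with Adm at 1.70 ± 0.086 (SE), Car9 at -3.46 ± 0.20 (SE) and P4ha2 at -1.56 ± 0.038 (SE). This list passed at adjusted p = 0.0491 without wild-type-labelled replicate 2, at 0.0475 without null-labelled replicate 3 and at 0.0394 with no filter on low counts. Of 47 nuclear-encoded respiratory chain genes, 15 were higher and 25 lower (median -0.15, camera adjusted p = 0.384), with Ndufb3 at -0.90 ± 0.060 (SE), Atp5o at -0.86 ± 0.033 (SE) and Ndufb7 at 0.84 ± 0.040 (SE). Of 29 genes of the unfolded protein and integrated stress responses, 9 were higher and 17 lower (median -0.28, camera adjusted p = 0.192), with Vldlr at -8.03 ± 0.22 (SE), Slc7a11 at -1.43 ± 0.055 (SE) and the chaperone Hspa5 at -1.18 ± 0.021 (SE).

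**Figure D2:**
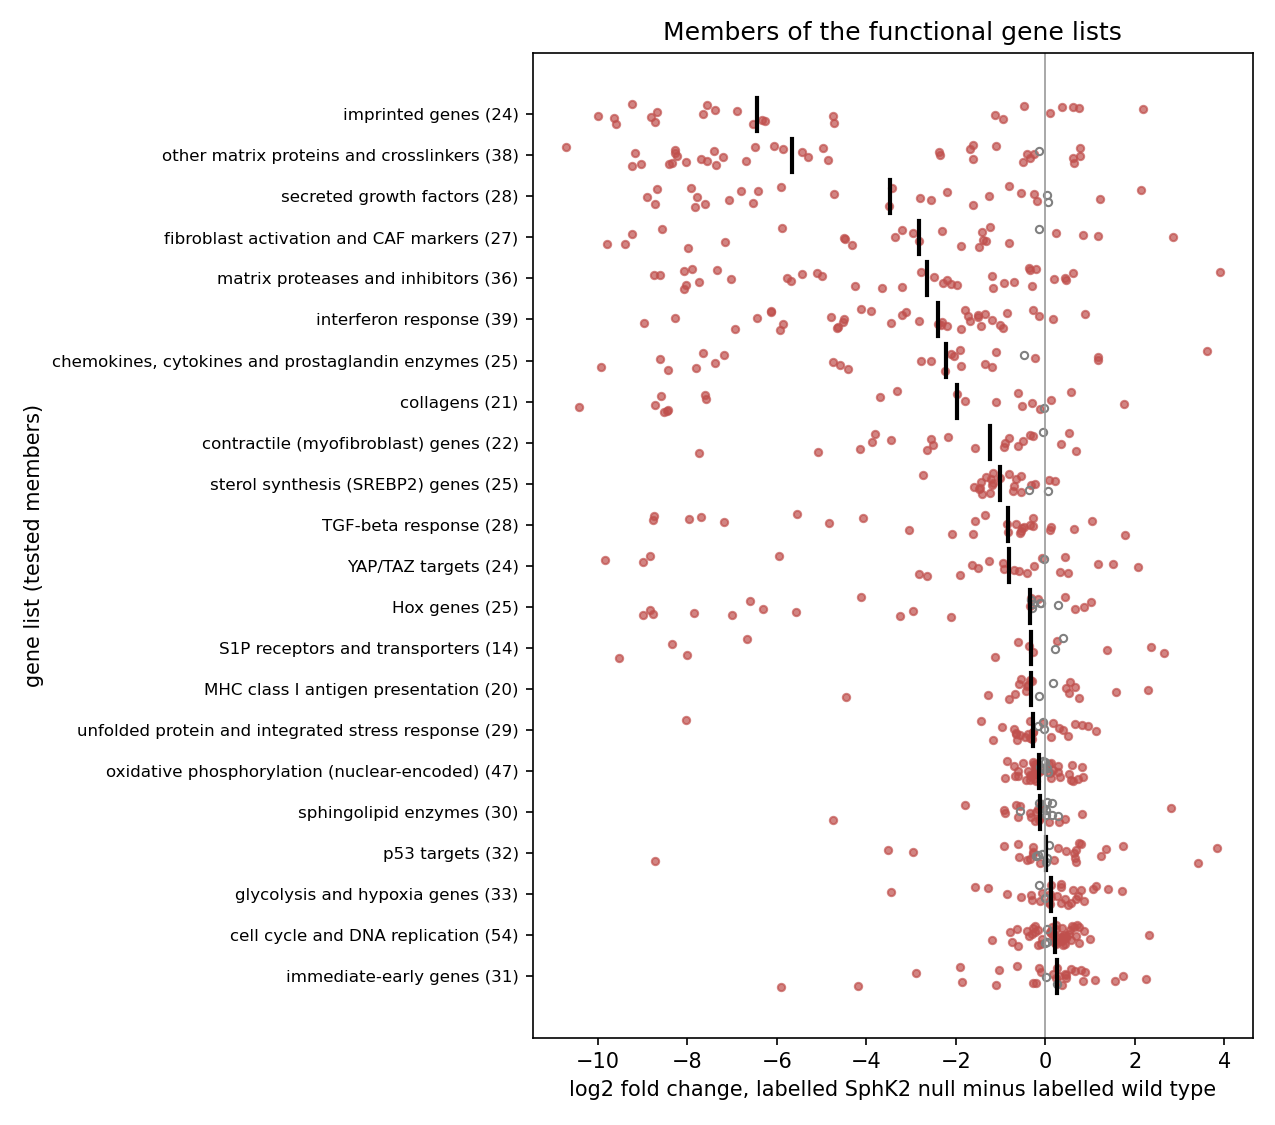
Log2 fold change (null-labelled minus wild-type-labelled libraries, horizontal axis) of each tested member of the 22 functional gene lists, filled where the edgeR adjusted p was under 0.05 and open otherwise, with the list's median as a black bar and the number of tested members in parentheses. Medians range from -6.44 in the imprinted genes to 0.26 in the immediate-early genes.

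In all, camera called 13 functional lists lower and 1 higher with the preset correlation of 0.01, and 4 of these calls held with an estimated correlation. The 4 were the matrix proteins, the matrix proteases, the chemokine list and the secreted growth factors. The estimated correlation was below the preset one for the proteases (-0.00702), the chemokine list (-0.0356) and the growth factors (-0.0047), and their adjusted p still rose. This setting thus changed more than the correlation, and the lost calls cannot be laid to correlation between genes alone. Adjusted over the list alone, the counts of higher and lower members were the same in 20 of the 22 lists. Adjusted over the list alone, 19 contractile genes were lower and 5 S1P receptors and transporters were higher.

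Tested markers of other cell types moved in both directions in each of the 7 lists. The neural and glial list (median log2 fold change -6.28) and the adipocyte list (-4.82) had the lowest medians. Of 5 tested epithelial markers, 2 were higher and 2 lower, and keratin Krt8 stood at 397 ± 13.4 CPM in null-labelled and 107 ± 1.80 CPM in wild-type-labelled libraries (SD, n = 3). Of 9 neural and glial markers, 2 were higher and 6 lower. The transcription factor Sox2 stood at 112 ± 0.568 CPM in wild-type-labelled and 0.093 ± 0.071 CPM in null-labelled libraries, and Stmn2 at 42.6 ± 0.838 against 0.202 ± 0.189 CPM (SD, n = 3). Of 10 chondrocyte and osteoblast markers, 3 were higher and 7 lower, with Dmp1 at -6.28 ± 0.32 (SE) and the osteoblast factor Sp7 at -5.28 ± 0.27 (SE). Of 7 adipocyte markers, 2 were higher and 5 lower. Cebpa had 475 counts against 1 (ratio 457, 95% counting interval 81.6 to 18100), and lipoprotein lipase, Lpl, stood at 29.0 ± 1.40 against 0.106 ± 0.048 CPM (SD, n = 3). Of 5 endothelial markers, 3 were higher, among them Egfl7 at 1.04 ± 0.076 (SE), and 2 lower, among them Plvap at -1.44 ± 0.19 (SE). Of 5 macrophage and leukocyte markers, 2 were higher and 3 lower, among the latter Cd14 at -1.73 ± 0.10 (SE) and Cd68 at -0.72 ± 0.18 (SE). The higher members, named after their values were seen, were Lyz2, the lysozyme of myeloid cells, with 2 counts against 152 (ratio 79.0, 95% counting interval 21.5 to 658), and Csf1r at 1.84 ± 0.38 (SE). Of 7 skeletal muscle markers, 2 were higher, Mylpf at 2.20 ± 0.18 (SE) and Tnnt1 at 1.80 ± 0.18 (SE), and 2 lower. Adjusted over the list alone, the counts of all 7 marker lists were the same.

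Genes of 7 of the 20 chromosomes were shifted as a set between the labels. Genes of chromosome 8 were higher in the null-labelled libraries, with a median log2 fold change of 0.64 over 781 genes (95% bootstrap interval 0.59 to 0.67), of which 80.3% lay above 0. Genes of chromosome 16 were lower, with a median of -0.46 over 443 genes (interval -0.52 to -0.41), and so were those of chromosome 14 (-0.34 over 482 genes) and chromosome 1 (-0.31 over 968 genes). Smaller shifts passed for chromosome 6 (0.30 over 810 genes), chromosome 3 (-0.22 over 826 genes) and chromosome 7 (0.18 over 1140 genes), which carries Sphk2. In windows of 10 Mb, the medians all lay on the same side of that of all genes only for chromosomes 8, 14 and 16. On chromosome 7, the windows starting at 20, 30 and 40 Mb had medians of 0.596, 0.563 and 0.51, and that at 50 Mb had -0.305. Sphk2 lies in the window that starts at 40 Mb. Camera over the 20 chromosomes gave adjusted p = 4.95e-13 for chromosome 8, 3.13e-08 for 16, 1.37e-05 for 14, 0.000142 for 1, 0.00381 for 6, 0.00598 for 3 and 0.027 for 7. With an estimated correlation, chromosomes 3 and 7 missed the threshold at adjusted p = 0.0556 and adjusted p = 0.052, and chromosome 4 (median -0.15) passed at adjusted p = 0.00714 against 0.0522 with the preset one. With no filter on low counts, chromosomes 3, 6 and 7 missed it at adjusted p = 0.119, 0.0932 and 0.0932.

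**Figure D3:**
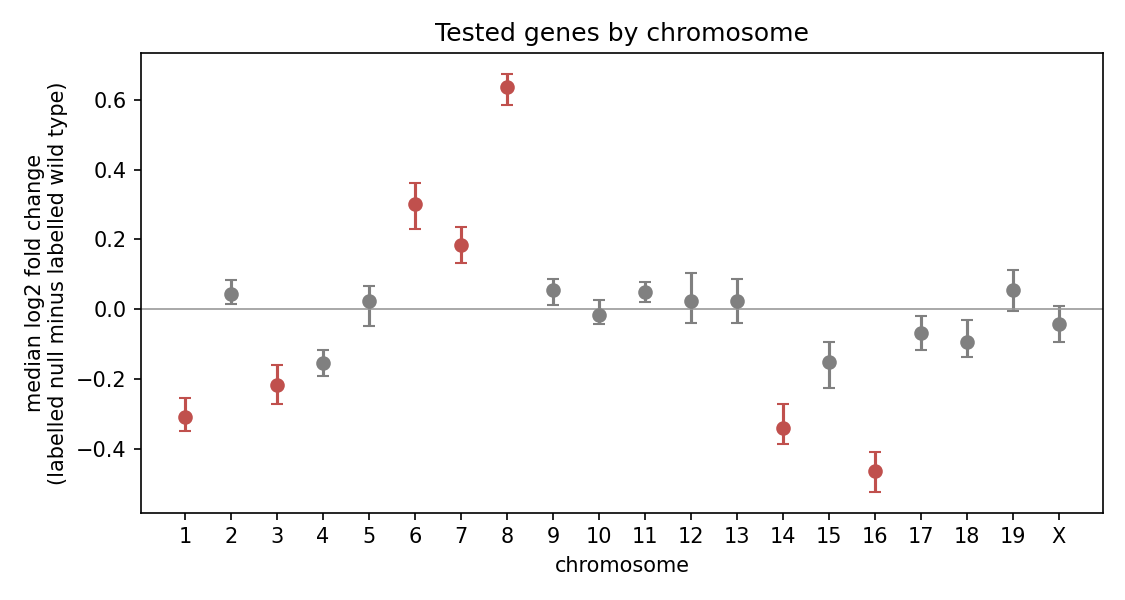
Median log2 fold change (null-labelled minus wild-type-labelled libraries) of the tested genes of each chromosome, with the 95% bootstrap interval over genes as error bar and in red the 7 chromosomes past camera's adjusted p of 0.05. Chromosome 8 has the highest median (0.64) and chromosome 16 the lowest (-0.46).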

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

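All alternatives here were chosen in advance. The 4 counts of genes moved by less than 1.5-fold in all 13 alternatives: genes higher ran from 5250 to 6011, lower from 5838 to 7303, over 2-fold higher from 1370 to 2113 and over 2-fold lower from 2114 to 3378. Every alternative scaled the libraries as if most genes did not change, while 79.2% of tested genes passed the threshold. The split into higher and lower genes depends on that scaling, which these alternatives do not test. The 98 genes taken by the naming rule kept their direction and side of the threshold in all 1176 values from 12 alternatives. Of 462 values of the lists and chromosomes, 441 kept their side of the threshold and none changed direction past it. With an estimated correlation in camera, 10 lists lost their call at unmoved medians: contractile genes (-1.24), activation markers (-2.83), collagens (-1.98), TGF-beta response (-0.84), YAP/TAZ targets (-0.81), interferon response (-2.40), cell cycle (0.21), sterol synthesis (-1.01), Hox genes (-0.34) and imprinted genes (-6.44). In the other alternatives the adjusted p of these 10 reached at most 0.0233. That setting also ended the calls of chromosomes 3 (-0.22) and 7 (0.18) and called chromosome 4 (-0.15). With no filter, the glycolysis list was called (0.11), and chromosomes 3 (-0.22), 6 (0.19) and 7 (0.13) were not. With over 1 CPM in 3 libraries, chromosomes 4 (-0.16) and 15 (-0.17) were called. Over all alternatives the adjusted p ran from 0.00289 to 0.119 for chromosome 3, from 0.00714 to 0.293 for 4, from 0.00259 to 0.0932 for 6, from 0.019 to 0.0932 for 7 and from 0.0441 to 0.143 for 15. Leaving out 1 library gave glycolysis medians from 0.13 to 0.17, called without wild-type-labelled replicate 2 (adjusted p = 0.0491) or null-labelled replicate 3 (0.0475), where the adjusted p ran from 0.0475 to 0.0835. Over all alternatives it ran from 0.0394 to 0.477. For these calls the cause was not tested. With the replicate number as a block, 5765 genes were higher and 6238 lower. Libraries of the same number did not visibly deviate together (r of 0.0123, -0.0028 and 0.0181 across genes), and not every library correlated best with its own number. No pairing by number was thus seen, which does not show that libraries of the same number were handled apart. Which genes were limited by the depth, 15598566 counts or more per library, was not tested.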

Other observations

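The genes of the next 2 paragraphs were chosen after their values were seen, and so were the tests on Sphk2, on the origin of the cells and on an extra copy of chromosome 8. The plan did not single out chromosome 8 for the other tests on it either. Cdkn2a and Cdkn2b, neighbours on chromosome 4 that encode inhibitors that arrest the cell cycle in cultured fibroblasts, were nearly absent from the null-labelled libraries. Cdkn2a stood at 282 ± 4.15 CPM in wild-type-labelled and 0.453 ± 0.088 CPM in null-labelled libraries (SD, n = 3), and Cdkn2b at 43.7 ± 1.87 against 0.088 ± 0.057 CPM (SD, n = 3). The neighbouring Mtap stood at 416 ± 6.72 against 181 ± 1.58 CPM (SD, n = 3). Xist, the RNA that coats the inactive X chromosome, stood at 688 ± 31.4 against 1.96 ± 0.304 CPM (SD, n = 3). The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had at most 5 counts in any library of either group, and genes of the X chromosome as a whole had a median log2 fold change of -0.04 (camera adjusted p = 0.725).

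Of the Hox genes, those of the HoxA cluster on chromosome 6 had the lowest median. All 10 tested HoxA genes were lower in the null-labelled libraries (median log2 fold change -6.66, and -6.25 with members at 0 counts at their bound), while the median was 0.18 over 4 HoxB genes, -0.09 over 5 HoxC genes and -0.33 over 6 HoxD genes. Hoxa10 stood at 83.7 ± 0.582 against 10.7 ± 1.38 CPM and Hoxd8 at 49.7 ± 2.45 against 44.6 ± 1.87 CPM (SD, n = 3). Hoxd8 does not stand for its cluster, since of the 6 HoxD genes 4 were lower and 1 higher. Over 2-fold lower were 12 of the 25 Hox genes, more than the 10 tested in HoxA, so some genes of other clusters were strongly lower too. The difference between clusters was not tested. The X-linked homeobox gene Esx1 and the transcription factor Hand1, both known from the placenta, were higher, Esx1 at 10.8 ± 0.856 against 1246 ± 28.5 CPM and Hand1 at 0.136 ± 0.034 against 20.05 ± 0.213 CPM (SD, n = 3). Of 3 transcripts from the fibroblast and collagen lists, vimentin (Vim) stood at 5622 ± 115 against 3211 ± 17.9 CPM, Pdgfra at 250 ± 7.504 against 89.4 ± 1.19 CPM, and Col1a2 at 2605 ± 43.1 against 7.39 ± 0.488 CPM (SD, n = 3).

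Sphk2 counts were higher in the null-labelled libraries by a log2 fold change of 0.8705 (0.77 to 0.97, 2 SE either side). An exchange of the labels between the groups stays open, since the counts cannot show which exons each group lacks. Reads of Rpl18 counted to Sphk2 are argued against, since reads over exons of both genes are left uncounted and 0 exonic bases of Sphk2 lie inside Rpl18 but outside its exons. A gain of the region stays open too, since the 132 tested genes within 5 Mb had a median of 0.5096 (95% bootstrap interval 0.37 to 0.65), with quartiles of -0.15 and 0.95. Reads from the introns of Dbp, which hold 198 exonic bases of Sphk2, and a real difference in Sphk2 expression were not tested.

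Most tested genes differed, and unequal depth is argued against, since the data thinned to the smallest library still gave 11610 genes past the threshold against 12040. A small spread within groups stays open for the 66.9% of calls under 2-fold. Of the 3982 genes over 2-fold, 83.27% were over 2-fold apart between even the closest libraries of the groups, which does not decide the matter because these genes were selected for that size. Separate origins of the cells, rather than genotype, cannot be told apart from the label, since the labels name no separate populations within a genotype, and the 7 chromosomes past the threshold are what such origins could bring. Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, and with the real one included, 1 gave as many genes as the real one (12040, with 0 in the highest other) and 1 as many over 2-fold (3982, with 0), while 2 gave as many lists (14, with 14) and 2 as many chromosomes (7, with 7), and these other splits each keep part of the difference between the labels.

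Chromosome 8 lay above the median of all genes by a log2 shift of 0.6568 (95% bootstrap interval 0.61 to 0.69). The shift is a median over 781 genes, which a few strong genes could hardly move, so the windows do not test that explanation. They show that the shift was spread along the chromosome: 100% of its 13 windows of 10 Mb had a median above that of all genes. After a correction for GC content and gene length, available for 99.5% of its genes, a shift of 0.5765 was left (interval 0.52 to 0.64) of 0.655. An extra copy of the chromosome in the null-labelled cells is a candidate explanation that stays open, as do other copy numbers and a change of expression: the log2 shift of 0.585 that a 1.5-fold dose would give lies below the uncorrected interval and inside the corrected one. Copy number was not measured.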
